A study of Mus musculus with 6 samples.

How the data were processed

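The data were 6 RNA-seq libraries of the cerebral cortex of C57BL/6 mice at postnatal day 7, 3 from control brains and 3 from Qk knockout brains. Groups and replicate numbers were taken from the sample titles and genotype labels. Per the labels' protocols, RNA was purified on columns, polyadenylated RNA was selected on oligo-dT beads, and libraries were built with the Ion Total RNA-Seq Kit on the AB Library Builder and sequenced on the Ion Proton. Reads were processed with STAR 2.4.1d and RSEM 1.3.0 against mouse builds mm10 and GRCm38.p4, per the submitters' processing notes. The order of these steps, the gene annotation and the read trimming are not given in the sources used here. The deposited files give 1 TPM value per gene and sample, under an Entrez number and a symbol, and sum to 1000000 in each library. TPM made by the authors divides a gene's estimated reads by its length and scales to the library total, so a rise of abundant genes lowers all others, and the number of reads and the counting error of a gene cannot be recovered. The depth of the libraries is therefore unknown and no interval from counts was computed. The labels say that the libraries came from separate brains, so p-values measure the spread between these brains.

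No pair of libraries was a duplicate: between 50 and 75 of the 14994 tested genes had identical values in any pair. Pearson correlations of log2(TPM + 1), across genes, were 0.978 to 0.982 within groups and 0.977 to 0.980 between groups. The symbols in the files were matched to the GENCODE annotation of GRCm38 by Entrez number, or by symbol where that failed, for coordinates, gene length, GC content and 3' UTRs. Of the tested genes, 97.23% had a match. No mitochondrially encoded gene was among the gene rows, so the list of such genes has no value.

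The main test was fixed before the data were examined. TPM were used as deposited, without further scaling. Genes with a mean of at least 1 TPM over the 6 libraries were kept, and log2(TPM + 1) was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend), with group as the only term. Moderated two-sided p-values were adjusted by Benjamini-Hochberg over the 14994 genes, with a threshold of 0.05. All log2 changes are on the log2(TPM + 1) scale, knockout minus control, which understates the change of genes of low TPM. All adjusted p-values of genes in the report are from this fit unless another setting is named.

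Gene lists were also fixed before the data were examined. They covered oligodendrocyte precursors, newly formed oligodendrocytes, myelin, astrocytes, radial glia and neural stem cells, gliogenic regulators, neurogenic progenitors, cell cycle, excitatory neurons, interneurons, synapse, cholesterol synthesis, fatty acid synthesis, regulators of splicing, microglia, endothelium, pericytes, meningeal fibroblasts, choroid plexus and ependyma, red blood cells, striatum, thalamus, hippocampus, immediate early genes, interferon response, reactive astrocytes and the unfolded protein and integrated stress response. Of their members, 444 genes were tested, and 21 of the 58 genes past the threshold belonged to a list. Each list was tested with limma's camera (preset correlation 0.01), adjusted over the 27 lists, and beside it with a correlation estimated from the data and with fry, whose mixed p was not among the tests set in advance. Camera compares a list with the other genes, while fry asks whether the list's genes move one way on balance. Members were also adjusted over the list alone. Some genes sit in 2 lists.

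The named genes followed a rule fixed before the data were examined. Of the 58 genes past the threshold, 4 were predicted or clone-based models and were not named. The rule took Qk, the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 2 TPM, no overlap of the groups and a symbol that is not a predicted or clone-based model, and from each list up to 4 members past the threshold with the smallest p or, where none passed, the 2 members of highest mean TPM. Genes named outside that rule, among them Fgfr3, Gja1, Aqp4, Gfap, Aldh1l1, Pdgfra, Trf, P2ry12, Csf1r, Ttr and members that passed over a list alone, were chosen after their values were seen. Values of a few genes are not reported here. Y-linked genes and Xist served as a check of the libraries only.

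The gene test was tested on simulated data, made from the means and SDs of these 14994 genes with 200 genes changed. It recovered 29% of genes changed by 0.5 and 73% of genes changed by 1 on the log2 scale, and 8.11% of its calls were unchanged genes. With no gene changed it called 1 gene. Camera found 100% of simulated lists of 20 genes shifted by 0.3 and 4% of unshifted lists at p under 0.05. The simulated genes varied independently of each other. These list shares therefore do not cover lists whose genes vary together, such as astrocytes, with an estimated correlation of 0.127. With 3 libraries per group, most simulated changes of 0.5 on the log2 scale were therefore missed.

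Alternatives tried were other pseudocounts and expression filters, median-of-ratios and quantile scaling between libraries, robust and untrended variance estimates, the replicate number as a block, a within-library correction for GC content and transcript length, both together, other windows around Qk, and leaving out each library in turn. Removal of mitochondrially encoded genes, also intended, was not run. The region around Qk was tested with Fisher's exact test, and the relation to gene length with a Spearman correlation across genes. Matched sets for 3' UTR sites were drawn with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.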

Results

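Polyadenylated RNA of the cerebral cortex was sequenced on the Ion Proton system from C57BL/6 mice at postnatal day 7. The libraries came from 3 control brains, whose genotype label was wild type, and from 3 brains labelled as Qk knockouts. Qk encodes quaking, an RNA-binding protein of glial and neural progenitor cells that takes part in splicing, stability and translation of the transcripts it binds. The question behind the comparison, from the title of the series, was how quaking bears on the turn of neural stem cells from making neurons to making glia. Expression was given for 35857 genes as TPM, a length-scaled transcript abundance with the same total in every library. Between 18971 and 19710 genes per library had a TPM above 0, and 14897 to 15074 reached a TPM of 1. The number of reads behind each value is unknown, since TPM keeps no depth. Tuba1a, an alpha-tubulin of young neurons, was the most abundant transcript in all 6 libraries, and the 100 most abundant genes took 23.7% to 25.2% of the TPM of a library. The first principal component held 24.6% of the variance and placed the 3 control libraries on one side and the 3 knockout libraries on the other.

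Qk itself fell in the knockout cortex. It was at 36.5, 43.2 and 41.3 TPM in control replicates 1, 2 and 3 and at 14.6, 15.2 and 15.4 TPM in knockout replicates 1, 2 and 3. The mean went from 40.4 ± 3.48 TPM (SD, n = 3) to 15.1 ± 0.39 TPM (SD, n = 3), which was 0.373 times the control level. The log2 change was −1.36 with a standard error of 0.0945 (limma, adjusted p = 0.000855). Qk (Entrez 19317) lies on the minus strand of chromosome 17, from 10202601 to 10319854 in GRCm38. The value sums all transcripts of the gene. The removed exons, and whether the deletion was limited to some cells, are not given in the sources used here.

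Beyond Qk, most genes that passed the test were lower in the knockout. Of 14994 genes tested with limma, 58 passed an adjusted p of 0.05, and of these 43 fell and 15 rose. All 58 had knockout values that did not overlap the control values, a separation seen in 14.18% of all tested genes and given by chance to 10%. Of the 58, 17 fell and 6 rose at least 2-fold on the log2(TPM + 1) scale. At an unadjusted p under 0.05 there were 1307 genes, against 750 expected by chance. Apart from predicted and clone-named genes, the falls of largest size were those of Abhd3, a phospholipase (25.2 ± 1.47 to 6.08 ± 1.06 TPM, log2 change −1.90), Kcne1l (26.1 ± 3.60 to 6.84 ± 0.364 TPM, −1.78) and Slc25a18, a mitochondrial glutamate carrier (90.9 ± 13.2 to 28.4 ± 4.17 TPM, −1.65). Tmem100 (−1.24) and Entpd2, an enzyme that breaks down extracellular ATP (−1.22), fell as well. Among the rises were A2m, the protease inhibitor alpha-2-macroglobulin (5.55 ± 0.736 to 21.2 ± 4.02 TPM, log2 change 1.75), Emp1 (1.37), Myoc, which encodes myocilin (8.32 ± 0.760 to 22.4 ± 0.602 TPM, 1.33), Vit (0.96), Lrrc23 (0.91) and Lfng, a modifier of Notch receptors (0.89). Glycam1 went from 0.41 ± 0.396 to 5.68 ± 1.04 TPM and Gpnmb from 0.927 ± 0.354 to 6.16 ± 2.45 TPM (all SD, n = 3). The number of genes past the threshold changed when 1 library was left out, which also leaves fewer samples in the fit. It was 59, 27 and 31 without control replicates 1, 2 and 3. Without knockout replicates 1, 2 and 3 it was 40, 28 and 34. Of 32 named genes past the threshold besides Qk, 15 also passed it in each of the 6 fits that left out a library; of those in this paragraph, Glycam1 was lost without knockout replicate 2 (adjusted p = 0.0634), Lrrc23 and Lfng passed in 1 of the 6 fits (highest adjusted p = 0.0862 and 0.159) and Gpnmb in 0 of 6 (0.0526 to 0.1).

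**Figure D1:**
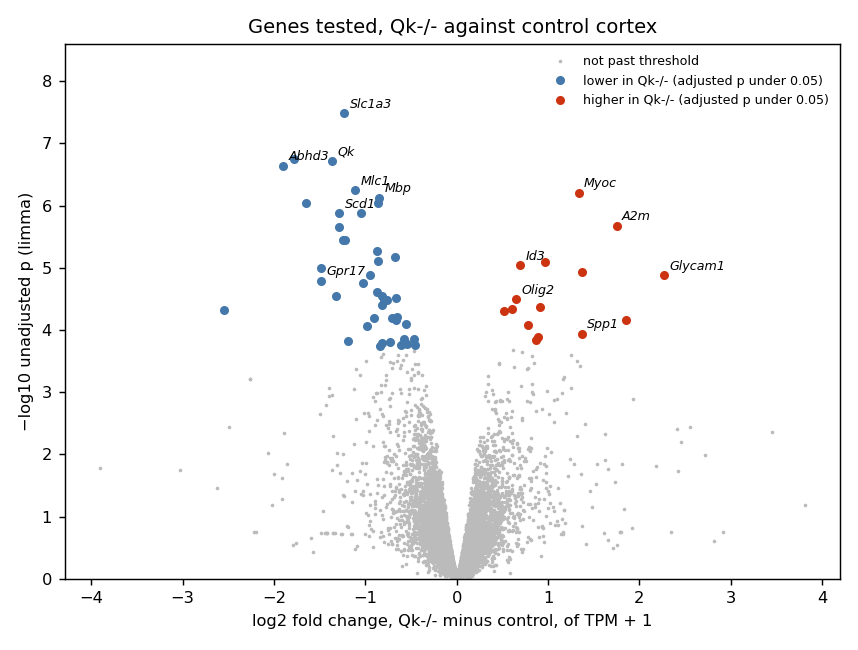
Log2 fold change of TPM + 1 (knockout minus control, horizontal axis) against −log10 of the unadjusted limma p (vertical axis) for the 14994 genes tested. Blue points are the 43 genes that fell and red points the 15 that rose at an adjusted p under 0.05, and grey points are the remaining genes.

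Astrocyte genes fell as a group, and unevenly. Of 26 members of the astrocyte list, 6 fell and none rose at the threshold over all genes; adjusted over the list alone, 15 fell and 2 rose (Aldh1l1 and Ppp1r3c). Slc1a3, the glutamate transporter GLAST, had the smallest p of all genes and fell from 265 ± 11.3 to 112 ± 4.86 TPM (SD, n = 3; log2 change −1.23, SE 0.0694, adjusted p = 0.000494). Mlc1, a membrane protein of astrocyte endfeet, fell from 196 ± 19.9 to 89.9 ± 4.82 TPM, and S100b, a calcium-binding protein, from 24.2 ± 2.56 to 9.30 ± 1.02 TPM. Acsbg1, a long-chain acyl-CoA synthetase, fell from 103 ± 4.67 to 65.1 ± 5.86 TPM. The other two were Fgfr3 (log2 change −0.67) and the gap junction gene Gja1 (−0.47). Several abundant astrocyte transcripts did not pass: the water channel Aqp4 was at 49.1 ± 3.29 and 46.4 ± 1.86 TPM, Gfap at 178 ± 6.27 and 156 ± 16.8 TPM, and Aldh1l1 at 55.5 ± 7.22 and 77.0 ± 4.93 TPM in control and knockout. The median log2 change of the list was −0.42, and limma's camera test placed it below other genes (adjusted p = 3.27e-13; adjusted p = 0.148 with an estimated correlation; fry adjusted p = 0.0114). In the fits that left out a library, Slc1a3, Mlc1 and S100b passed in all 6, Acsbg1 in 2 (highest adjusted p = 0.0817) and Fgfr3 and Gja1 in 0 (highest adjusted p = 0.116 and 0.188).

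**Figure D2:**
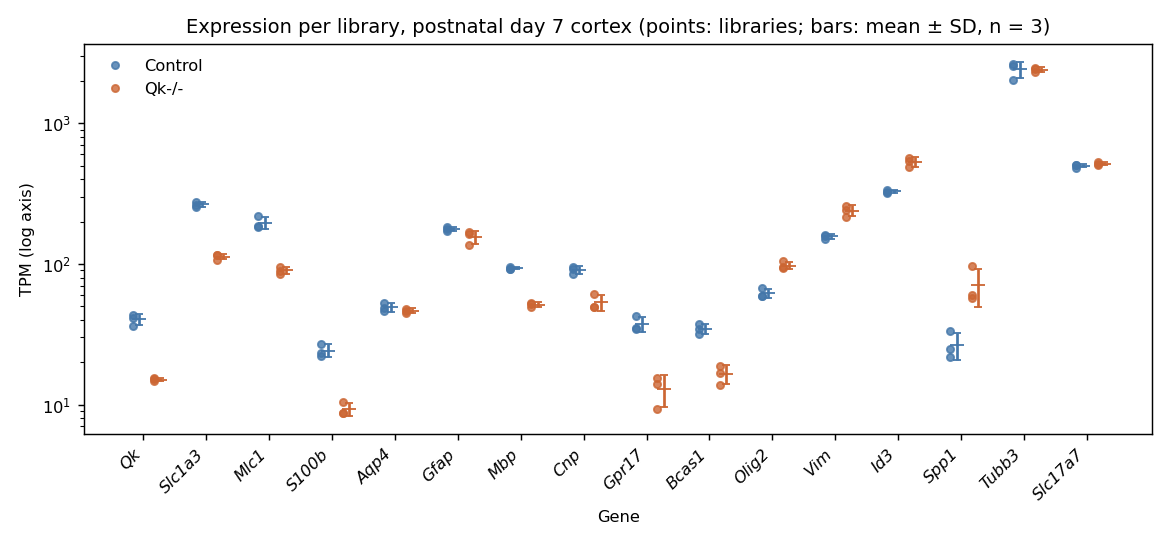
TPM on a log axis (vertical) of genes named in the text (horizontal) in the 3 control libraries (blue points) and the 3 knockout libraries (orange points), with bars for the mean ± SD (n = 3). The knockout libraries lie below the control libraries for Qk, Slc1a3, Mlc1, S100b, Mbp, Cnp, Gpr17 and Bcas1 and above them for Olig2, Vim, Id3 and Spp1.

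Within the oligodendrocyte lineage, genes of newly formed and myelinating cells fell while Olig2 rose. Gpr17, a receptor of cells leaving the precursor stage, fell from 37.5 ± 4.78 to 12.9 ± 3.24 TPM, and Bcas1, a marker of early myelinating cells, from 34.6 ± 2.94 to 16.5 ± 2.46 TPM. Mbp, the myelin basic protein gene, fell from 93.5 ± 1.5 to 51.4 ± 1.85 TPM (log2 change −0.85, SE 0.0694, adjusted p = 0.00153). Cnp, which encodes a myelin-associated phosphodiesterase, fell from 90.9 ± 5.40 to 53.3 ± 6.66 TPM. Olig2, a transcription factor of the lineage, rose from 61.8 ± 4.64 to 97.3 ± 6.01 TPM (all SD, n = 3; log2 change 0.65, SE 0.0837, adjusted p = 0.0152). Of 14 genes of newly formed oligodendrocytes, 3 fell (Gpr17, Bcas1 and Sirt2) and none rose, with 4 falls, Neu4 added, when adjusted over the list alone (median −0.18; camera adjusted p = 0.000114; adjusted p = 0.148 with an estimated correlation; fry adjusted p = 0.0114). Of 20 myelin genes, 3 fell (Mbp, Car2 and Cnp) and none rose, with 5 falls (Fa2h and Ugt8a added) and 2 rises adjusted over the list alone (median −0.16; camera adjusted p = 0.0141; adjusted p = 0.239 with an estimated correlation; fry adjusted p = 0.0114). Trf, which encodes transferrin, went from 24.0 ± 2.17 to 37.3 ± 3.12 TPM (adjusted p = 0.0528). The camera result of the myelin list was lost when no expression filter was used (adjusted p = 0.152). Of 18 precursor genes, Olig2 alone passed, and 2 rose (Olig2 and Olig1) and 2 fell (C1ql1 and Pdgfra) adjusted over the list alone; Pdgfra was at 41.5 ± 0.909 and 33.5 ± 1.54 TPM (adjusted p = 0.241), and the list as a whole did not pass (camera adjusted p = 0.0965). Among these genes Mbp passed in all 6 fits that left out a library. Bcas1 was lost without control replicate 2 (adjusted p = 0.0644) and Gpr17 without control replicate 3 (adjusted p = 0.0547), while Olig2 and Car2 passed in 3 of the 6, Cnp in 2 and Sirt2 in 1, with highest adjusted p of 0.0817, 0.0664, 0.0893 and 0.116.

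Genes of radial glia and neural stem cells went both ways. Id3, an inhibitor of basic helix-loop-helix transcription factors, rose from 328 ± 8 to 532 ± 42.4 TPM, and the intermediate filament gene Vim rose from 157 ± 6.17 to 239 ± 21.6 TPM. Ednrb, the endothelin B receptor, fell from 58.7 ± 6.67 to 32.7 ± 2.73 TPM and Hopx from 40.4 ± 2.17 to 23.0 ± 2.57 TPM (all SD, n = 3). These were the 2 rises and 2 falls among 19 members, with 4 and 4 adjusted over the list alone, where Lrig1 and Egfr joined the rises and Hes5 and Tnc the falls. The list had a median of 0.17 and a mean of 0.05 and stood above other genes (camera adjusted p = 0.0106; adjusted p = 0.333 with an estimated correlation; fry adjusted p = 0.204). Id3 passed in all 6 fits that left out a library, Hopx in 4, and Vim and Ednrb in 2 (highest adjusted p = 0.0893, 0.1 and 0.0664). None of 23 cell cycle genes passed the threshold over all genes and 1 rose adjusted over the list alone, yet 20 of the 23 had a positive log2 change, with a median of 0.24 (camera adjusted p = 9.03e-07; adjusted p = 0.148 with an estimated correlation; fry adjusted p = 0.0504). Pcna was at 99.1 ± 5.13 and 118 ± 12.7 TPM, and Hmgb2, the member that passed over the list alone, at 52.0 ± 0.119 and 68.8 ± 7.08 TPM. None of 16 gliogenic regulators passed by either adjustment (median 0.07; camera adjusted p = 0.112). Nfix, a nuclear factor I gene, was at 114 ± 8.58 TPM in control and 114 ± 9.30 TPM in knockout cortex. That list was past the threshold without control replicate 3 (camera adjusted p = 0.0317) and after correction for GC content and length (0.0442).

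Neuronal genes showed no change at the threshold. None of 14 genes of neurogenic progenitors and newborn neurons passed by either adjustment (median 0.01, mean −0.01; camera adjusted p = 0.857). Tubb3, a tubulin of young neurons, was at 2410 ± 327 and 2400 ± 97.0 TPM, and Dcx, the doublecortin gene of migrating neurons, at 78.2 ± 3.00 and 78.7 ± 5.73 TPM. The 20 genes of excitatory cortical neurons (median −0.02, mean 0.003, camera direction up; adjusted p = 0.451) and the 20 of inhibitory interneurons (median 0.004, mean −0.03, camera direction up; adjusted p = 0.451) did not pass by any of these tests. Slc17a7, the vesicular glutamate transporter of cortical projection neurons, was at 499 ± 13 and 515 ± 12.9 TPM, and Sst, the somatostatin gene, at 1054 ± 141 and 1314 ± 61.9 TPM. The 25 synapse genes had a median of −0.10 (camera adjusted p = 0.158), with none past the threshold by either adjustment. The 26 regulators of splicing had a median of −0.01 and a mean of 0.02 (camera direction up; adjusted p = 0.324), with none past the threshold by either adjustment.

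Among genes of lipid synthesis, Scd1, a stearoyl-CoA desaturase, fell from 39.6 ± 1.94 to 15.8 ± 2.13 TPM (SD, n = 3; log2 change −1.29, SE 0.112, adjusted p = 0.00182). It was the one call among 16 genes of fatty acid synthesis and elongation, of which 4 fell adjusted over the list alone (Scd1, Scd2, Fads1 and Fads2; camera adjusted p = 0.0513). The list was past the threshold, downwards, in 4 of 19 other settings of the analysis, with the lowest adjusted p (0.0152) without knockout replicate 1. Of 23 genes of cholesterol synthesis none passed and 1, Tm7sf2, fell adjusted over the list alone (median 0.07; camera adjusted p = 0.0731). Hmgcs1, an early enzyme of the pathway, was at 359 ± 6.81 and 344 ± 39.7 TPM. This list was past the threshold, upwards, without knockout replicate 2 (adjusted p = 0.00976) and after median-of-ratios scaling (0.0449).

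**Figure D3:**
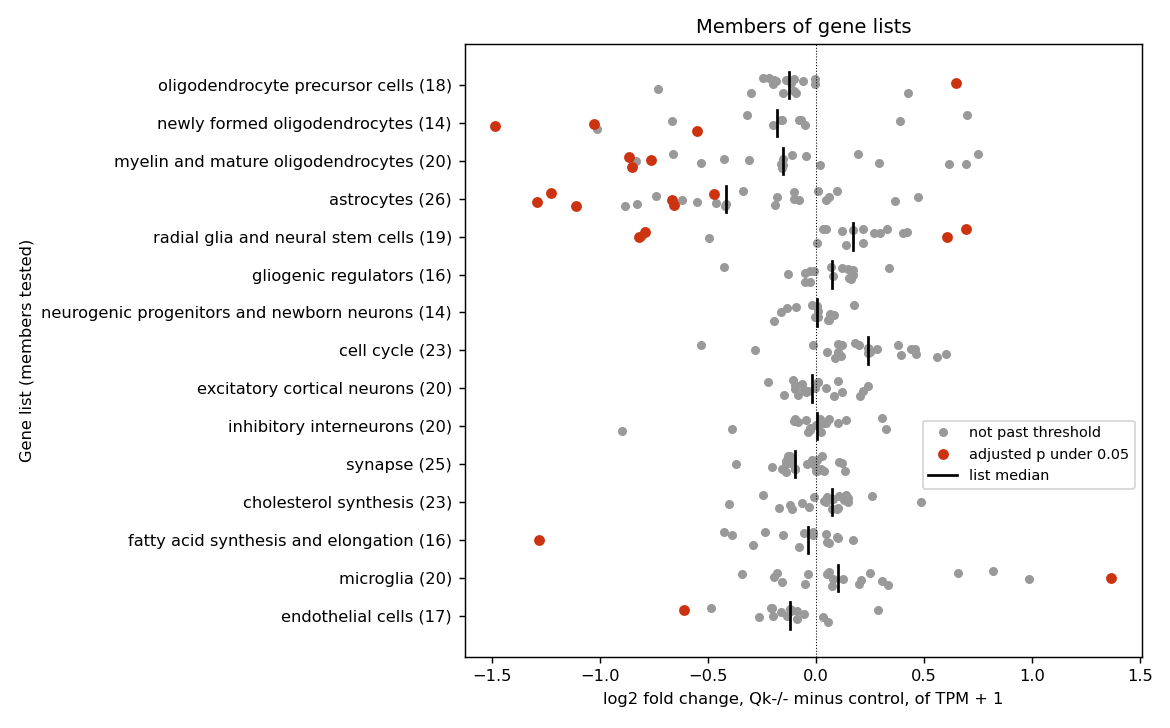
Log2 fold change of TPM + 1 (knockout minus control, horizontal axis) of each tested member of 15 gene lists (vertical axis, with the number of members). Red points passed an adjusted p of 0.05, grey points did not, and black bars mark list medians, which were −0.42 for astrocytes and 0.24 for cell cycle genes.

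Of the genes of other cells of the cortex, few passed the threshold over all genes. Spp1, the osteopontin gene, rose from 26.6 ± 5.88 to 71.1 ± 21.7 TPM (SD, n = 3; adjusted p = 0.0368) and was the one call among 20 microglia genes, with 4 rises adjusted over the list alone (Spp1, Cd14, Cd68 and Tyrobp). The microglia list stood above other genes (median 0.10; camera adjusted p = 0.000984; adjusted p = 0.254 with an estimated correlation; fry adjusted p = 0.185). Its surface receptors P2ry12 (12.1 ± 1.06 and 9.29 ± 0.321 TPM) and Csf1r (32.4 ± 4.32 and 31.2 ± 4.42 TPM) did not pass. Mfsd2a, a lipid transporter of brain endothelium, fell from 32.9 ± 3.43 to 21.1 ± 0.866 TPM (adjusted p = 0.0451), as the one member called among 17 endothelial genes by either adjustment. The endothelial list (median −0.12; camera adjusted p = 0.0223), 13 genes of pericytes and smooth muscle (−0.18; 0.00975) and 14 genes of meningeal fibroblasts (−0.17; 0.0215) stood below other genes. With an estimated correlation the adjusted p of these lists was 0.252, 0.384 and 0.535, and by fry 0.0114, 0.204 and 0.409. The pericyte list had 1 fall adjusted over the list alone (Vtn) and the meningeal list 0. Spp1 passed in 1 of the 6 fits that left out a library (highest adjusted p = 0.157) and Mfsd2a in 0 (0.169). The endothelial list did not pass without control replicate 1 (adjusted p = 0.0956) or knockout replicate 3 (0.0756), the pericyte list without knockout replicate 3 (0.187), and the meningeal list without control replicate 3 (0.0926), knockout replicate 1 (0.125) or knockout replicate 3 (0.187).

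The 12 immediate early genes, which neurons switch on with activity and handling, stood above other genes (median 0.23; camera adjusted p = 0.00242; adjusted p = 0.384 with an estimated correlation; fry adjusted p = 0.268). None of them passed over all genes and 1, Egr1, rose adjusted over the list alone. Foxj1, a transcription factor of ciliated cells, rose from 8.6 ± 1.48 to 16.4 ± 1.13 TPM (SD, n = 3; adjusted p = 0.0428, and 0.0518 to 0.159 when a library was left out). It was the one member called, by either adjustment, among 13 genes of choroid plexus and ependyma, a list that did not pass (camera adjusted p = 0.747). Ttr, the transthyretin gene of the choroid plexus, was at 1210 ± 423 and 783 ± 184 TPM. The lists for thalamus (11 genes; camera adjusted p = 0.0513), striatum (14; 0.5), hippocampus (10; 0.325), red blood cells (7; 0.136), interferon response (9; 0.0558), reactive astrocytes (12; 0.534) and the unfolded protein and integrated stress response (16; 0.582) did not pass, and none of their members did over all genes. Adjusted over the list alone, 1 hippocampal gene (Lhx9) and 1 stress response gene (Ddit3) fell. The striatum list had a median of −0.02 and a mean of 0.03. The interferon list was past the threshold, downwards, without control replicate 2 (adjusted p = 0.000998), control replicate 3 (0.0343) or knockout replicate 1 (0.0143), the red blood cell list, also downwards, without control replicate 3 (0.0134) or knockout replicate 1 (0.0137), and the thalamus list, upwards, without control replicate 3 (0.0254). Counting also the settings that kept all 6 libraries, such as the one with no expression filter, the interferon list passed in 8 of 18 settings, the red blood cell list in 5 of 19 (lowest adjusted p = 0.000614, with the replicate number as a block and correction for GC content and length) and the thalamus list in 6 of 19 (0.0192, with no expression filter), each in 1 direction. Of all 27 lists tested, 10 passed with camera's preset correlation, 0 with an estimated one and 4 by fry (astrocytes, newly formed oligodendrocytes, myelin and endothelium). Fry's mixed test, which counts changes in either direction, passed 12: these 4, radial glia, the cell cycle, microglia, oligodendrocyte precursors (adjusted p = 3.97e-05), the unfolded protein and integrated stress response (8.83e-05), fatty acid synthesis (0.000363), choroid plexus and ependyma (0.00209) and cholesterol synthesis (0.0164).

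None of the 65 tested genes within 5 Mb of Qk besides Qk passed the threshold, against 55 of the 14512 other annotated genes (Fisher's exact test, two-sided, p = 1). Across 14578 genes, which are not independent replicates, the log2 change had a Spearman correlation of −0.0574 with gene length. As a check of the libraries, knockout replicate 2 had 41.2 TPM of Xist and 0 TPM of Kdm5d, Uty, Ddx3y and Eif2s3y, the pattern of a female, while the other 5 libraries had 0 to 0.03 TPM of Xist and expressed those Y-linked genes.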

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

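All alternatives were chosen before the data were examined. Qk was past the threshold in every alternative, with a log2 change of −1.43 to −1.17, and each of the 58 genes kept its direction wherever it was tested. Of 542 values of the 32 named genes past the threshold, 429 passed again, 113 did not, and 0 reversed; of 612 values of 36 named genes that had not passed, 0 did. Of 357 values of 21 called genes chosen after their values were seen, 205 passed, and of 204 values of 12 uncalled ones 15 did, among them Trf, Hes5, Lgals3 and Lgals1. In 43 cases a value changed sign that was past the threshold neither in the result as reported nor in that alternative. The number of genes past the threshold ranged from 27 to 74. With no expression filter it was 37 (9 higher, 28 lower), with 23207 genes tested and 33 of the 58 among those found, and the myelin list had an adjusted p of 0.152. Without a variance trend it was 28 (8 and 20). Leaving out each library in turn gave 27 to 59 genes (6 to 21 higher, 20 to 38 lower), with fewer samples in the fit, and an adjusted p of 0.0317 to 0.372 for gliogenic regulators and 0.00976 to 0.361 for cholesterol synthesis. Median-of-ratios scaling brought the cholesterol list to 0.0449, and correction for GC content and length the gliogenic list to 0.0442 with 70 genes past the threshold; the cause was not tested.

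With a correlation estimated from the data, the adjusted p was 0.148 for newly formed oligodendrocytes, 0.239 for myelin, 0.148 for astrocytes, 0.333 for radial glia and 0.148 for the cell cycle. By fry it was 0.204 for radial glia and 0.0504 for the cell cycle. Over all alternatives these lists ranged from 2.98e-06 to 0.148, 0.00117 to 0.239, 2.91e-14 to 0.148, 0.00613 to 0.333 and 1.8e-07 to 0.148, and kept their direction. No gene near Qk passed in any alternative, and the correlation with length ranged from −0.091 to 0.00535, positive in the 2 fits corrected for GC content and length. The planned removal of mitochondrially encoded genes was not run, since no gene row held one.

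The replicate number as a block gave 38 genes (8 higher), 35 of them among the 58, and together with the correction for GC content and length 31 genes (6 higher, 25 lower) and an adjusted p of 0.0326 for the gliogenic list. The deviations of libraries with the same number correlated by only 0.035, 0.0311 and 0.0134, so the numbers were not taken to pair the brains. Each library did correlate best with its own number, a hint from the data and not from the design. TPM give no depth, so its limit on genes of low expression cannot be stated.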

Other observations

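Of the tests in this part, those on whether astrocyte, oligodendrocyte and microglia genes moved apart were chosen after the results were seen. So were the count of genes that passed without the female library and the genes named first. The rules for macrophages and the phagocytic state were written before those tests were run. They name Spp1 and Gpnmb, however, and so followed from results already seen. Those for 3' UTR sites were also written before they were run, and concern genes that fell in the main fit. Of the 58 genes past the threshold, 37 were on none of the lists. Plpp3, a lipid phosphate phosphatase, fell from 107 ± 5.94 to 58.1 ± 0.781 TPM and S1pr1, a receptor for sphingosine-1-phosphate, from 83.4 ± 4.26 to 45.3 ± 4.48 TPM (SD, n = 3; limma adjusted p = 0.00153 and 0.00505). Sfxn5, a mitochondrial carrier, fell from 55.7 ± 3.04 to 26.5 ± 2.21 TPM, Gldc, the glycine decarboxylase of the glycine cleavage system, from 31.8 ± 2.33 to 17 ± 0.721 TPM, and Ttyh1, a membrane protein, from 350 ± 13.6 to 219 ± 12.6 TPM. These 5 genes passed in each of the 6 fits that left out a library.

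Fgf1 fell from 10.5 ± 1.08 to 4.85 ± 0.705 TPM and Fgfbp3, which encodes a protein that binds fibroblast growth factors, from 19.0 ± 1.41 to 9.35 ± 0.682 TPM, and Fgfr3, which is on the astrocyte list, from 40.8 ± 3.25 to 25.3 ± 1.89 TPM. Angpt1, a ligand of the endothelial receptor Tek, rose from 7.58 ± 0.612 to 13.7 ± 0.655 TPM, and Tnfrsf19 from 59.9 ± 2.61 to 85.9 ± 1.24 TPM (SD, n = 3). Of the fits without 1 library, Fgfbp3 passed in 4 (limma adjusted p = 0.0524 without control replicate 2 and 0.0544 without control replicate 3), Fgf1 and Tnfrsf19 in 1 (highest adjusted p = 0.157 and 0.104), and Fgfr3 and Angpt1 in 0 (0.116 and 0.13).

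The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 58 genes, more than any other (1 of the 10 gave as many, itself), and the highest of the others gave 3. Knockout replicate 2 was the one female library. Without it, the log2 changes of the 58 genes were at a median of 0.9894 times their size with it (0.863 to 1.14). The fit without it, with fewer samples, found 28 genes, 27 of them among the 58. The ratio does not decide on the female library: all 58 genes were selected with it included and had separate groups, so a low ratio could hardly occur. The 27 genes passed among libraries of the male pattern only, which argues against the female library as the source of their differences. For the 31 genes that did not pass without it, the question is not decided.

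The genes of the astrocyte list, and those of the oligodendrocyte lists, did not all move alike; no list passed as a set with an estimated correlation. If astrocytes alone made the 26 astrocyte genes, a lower share of astrocytes would move these genes by about 1 factor. About 5% of members would then have a 95% interval that leaves out the list's median. In fact 69.23% did (18 of 26; Wilson interval 50.01% to 83.5%), 11 above and 7 below the median, against at most 19.23% in the other splits. For the 52 genes of the 3 oligodendrocyte lists the share was 32.69% (17 of 52, 21.52% to 46.24%), with 7 above and 10 below, against at most 5.769%. The other splits mix control and knockout libraries, which widens the intervals of genes that differ between the groups. Their shares can therefore be too low for a fair comparison. Both Wilson intervals take genes as independent, though all were measured in the same 6 brains, so they do not measure the spread between brains. The members of each group thus did not share 1 change. Neither percentage decides against a lower number of these cells, since genes also made by other cells would move by less. The 3 oligodendrocyte lists also cover different stages, which need not move alike. A smaller share beside a change within the cells stays open, as does a shift in their stage of maturation, which was not tested.

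Microglia genes also moved apart. Of 20 members, 35% had an interval that left out the list's median, against at most 15% in the other splits. Those splits again mix the groups, so their share can be too low. The Wilson interval of the 35% (7 of 20) was 18.12% to 56.71%, again with genes taken as independent. Genes also made by other cells would spread in this way too, so this does not decide against a larger share of microglia. Macrophages of the brain borders or blood cannot be told apart from microglia here: 9 of their genes had a median log2 change of 0.1276 (unadjusted camera p = 0.0389, p = 0.277 with an estimated correlation, fry p = 0.353), with 5 positive and 0 past the threshold. A candidate explanation is the phagocytic state of microglia known from early postnatal white matter, to which Spp1 and Gpnmb belong. Its 13 other tested genes stood above other genes (unadjusted camera p = 7.229e-05, and adjusted over 29 lists 0.000524 by camera, 0.119 with an estimated correlation and 0.013 by fry). Of these genes, 10 were positive and 0 past the threshold. The largest log2 changes were those of Lgals3 (1.25, at 3.53 ± 1.13 and 9.57 ± 1.48 TPM) and Lgals1 (0.63). Lpl was at 0.03, while Igf1 (−0.16), Cd63 (−0.15) and Ctsl (−0.06) had negative changes. Several of the 13 genes are also made by other brain cells.

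A hypothesis for the genes that fell is that they lost binding of quaking to their 3' UTRs. The core site ACTAAY (Y being C or T) was present in the annotated 3' UTR of 24 of the 40 fallen genes searched besides Qk, or 60%. In 10000 sets matched on UTR length and expression, drawn with replacement, the median was 35% (22.5% to 47.5%, one-sided p from these draws = 0.0002). Of the 15 genes that rose, 20% had a site, against 26.67% in their matched sets (one-sided p from the draws = 0.775). In sets matched on UTR length and A+T content, but not on expression, the median was also 35% (22.5% to 50%, one-sided p from the draws = 0.0006999). No sets were matched on expression and A+T content together. Among glial list genes, the 45 with a site changed by −0.2271 more on the log2 scale than the 52 without (one-sided permutation test, p = 0.00991). Among genes of the neuronal lists the same difference was −0.0476. The glial comparison was not matched on UTR length. It also holds fallen genes that gave the 60%, such as Slc1a3 and Mbp, so it is not separate evidence. It therefore does not decide whether sites are merely frequent in glial genes. Base composition is not settled. The site's excess over matched sets was 25.37 percentage points, and 0 of the other rearrangements of its bases had as large an excess. YTAACA came close, with an excess of 23.16 and the same one-sided p from 2000 draws (0.0004998). The median excess of the others was 4.195, so other orders of these bases also tended to be more frequent in the fallen genes. A small p from matched draws was therefore not particular to the site. Fewer than 6 others had as large an excess in only 75.7% of 1000 resamples of the genes. The site's rank was thus within its spread and was not taken to exclude base composition. Quaking may thus act on some of these transcripts directly, but a site in a 3' UTR does not show binding, and splicing cannot be seen in values per gene.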
